A study of Mus musculus with 12 samples.

How the data were processed

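RNA was sequenced from cultured mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos. The labels place the 12 libraries in 4 groups of 3: Ezh2a mutant, the littermate wild type of the Ezh2a mutant, Ezh2b mutant, and the littermate wild type of the Ezh2b mutant. Per the labels' protocols, poly-A RNA was selected with oligo-dT beads, fragmented, and copied into cDNA with random hexamers. The protocol as given names no step that marks the strand of the RNA. The deposited values are raw counts per gene symbol, in 1 table of 35602 symbols. Per the submitters' processing notes, fastp 0.21.0, HISAT2 2.1.0, StringTie 2.1.5 and edgeR 4.2.1 were used and the genome build was GRCm38 (mm10). The counting program, the annotation release and any strand setting are not given in the sources used here. A count of 1 occurred in 3357 cells of the table and a count of 2 in 13267, a pattern left when both mates of a read pair are counted or when StringTie coverage is converted to reads. Which of these applies is not known. Counts may exceed the number of sequenced fragments, and counts divided by 2 were tried as an alternative.

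Each column was assigned to its library by matching the column name with the sample's own description, and every column of values was assigned. Total counts per library ran from 28811482 to 54070380, and 18619 to 19891 genes had at least 1 count in a library. Of the symbols, 11119 were at 0 in all libraries. For positions, 25793 symbols had a single gene of that name in GENCODE M21 on GRCm38, and 1457 symbols were not in the RefSeq table of GRCm38.p6. Positions given for genes are those of GENCODE M21, matched by symbol. The libraries of a group were compared pair by pair. The mean chi-square per gene was 2.74 to 13.5 within groups and 17.0 to 89.6 between groups, and the median within groups was 0.851 to 2.14. The highest means, 12.3 and 13.5, are those of Ezh2b wild-type replicate 3 against the others of its group, and every other pair within a group was at 4.98 or lower. This library was also the deepest and had 2.13% of its counts in mitochondrial genes, against 1.76% and 1.72% in replicates 1 and 2. If both mates of a pair were counted, sampling noise alone would give a mean of 2, and the lowest medians are no higher than such noise. Some pairs of libraries may then differ by little more than sampling noise for most genes. Each library was still counted as a separate sample. The labels do not say whether the replicates of a group were separate cultures or embryos. The p-values therefore measure the spread between these samples, which may be partly technical.

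Genes were filtered with filterByExpr by group, which left 15708 genes, and libraries were scaled by TMM factors (0.977 to 1.03). A negative binomial model with 1 mean per group was fitted to all 12 libraries (8 residual degrees of freedom) with edgeR 4.0.16 in R 4.3.3. Contrasts were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), and p-values were adjusted by Benjamini-Hochberg over all tested genes. Every adjusted p of a gene comes from this test, and a gene is said to have risen, fallen or changed where it is under 0.05. A standard error is the size of the log2 fold change divided by the square root of its F statistic. The square root of the common dispersion was 0.047. Levels are CPM, counts scaled to a common library total, after TMM scaling, as mean and SD over 3 libraries. The comparisons were each mutant against its own wild type, the difference between the Ezh2b and the Ezh2a effect (an interaction contrast), and the Ezh2b wild type against the Ezh2a wild type. Each mutant has its own control libraries, so the Ezh2a and Ezh2b effects share none.

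Choices were made before the data were examined, except where the text says otherwise. They include 34 gene lists with 906 entries, 5 of which had no row in the count table. Lists with at least 3 tested genes were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, and again with an estimated correlation. Adjusted p-values of lists are over the 32 lists tested. The erythroid list had 2 tested genes and the X inactivation list 0, so neither was tested. Mitochondrial genes carry RefSeq names in the table and were matched to the list by their start and end on the mitochondrial genome. Counts of list members are over all genes tested, and beside them stand the counts adjusted over the list alone.

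Genes are named by a rule. Ezh2, Ezh1 and Cdkn2a are always given. For each mutant the 10 largest rises and the 10 largest falls are named among genes that changed, had an average log2 CPM of at least 1 and had all mutant libraries on the same side of all wild-type libraries, leaving out symbols that are only model names. Chance alone gives such a separation to 10% of genes with 3 libraries against 3. For the difference between effects, 5 genes per direction are named without the condition on libraries, and for the wild types 5 per direction with it. For lists that are described, up to 4 members with the smallest p are named. Of the genes picked by this rule, 2 are not reported here and were not replaced.

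The test was checked on counts simulated from the real means, library sizes and fitted dispersions for the Ezh2a comparison, over 15476 genes. The changed genes were drawn from those with an average log2 CPM of at least 1, so recovery at lower levels was not tried. Of 50 genes changed 1.25-fold, 70% were recovered, of 50 changed 1.5-fold 90%, and all of the 50 changed 2-fold and the 50 changed 4-fold. There were 11 false calls among 15246 unchanged genes. A shifted list was recovered and 0 of 20 random lists were called. Simulated genes varied independently, so this cannot show how often a list of correlated genes is called in error. Other splits of the real samples called 5 to 9 lists in the Ezh2a pair and 5 to 10 in the Ezh2b pair.

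Alternatives were DESeq2 size factors, library totals without TMM factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a fit to the 6 libraries of a pair, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a threshold of at least 2-fold, and an estimated correlation in camera. Chosen after seeing the data were thinning of every library to the smallest total, counts divided by 2, and leaving out the deepest libraries of the Ezh2b pair. Counts are sums per gene, so the isoforms of Ezh2 were not told apart. Antisense and overlapping genes cannot be separated without strand, and counts of close paralogs depend on how shared reads were assigned.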

Results

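Gene expression was measured by RNA sequencing in 12 cultures or samples of MEFs. The series compares mice with a mutation of either of 2 forms of Ezh2, called Ezh2a and Ezh2b, and its title describes isoforms of the EZH2 protein made from cryptic splice sites. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27. Each mutant was set against wild-type littermates of its own, with 3 libraries in every group. Total counts were 29175698 to 33780452 in the Ezh2a mutant libraries, 31051443 to 39344643 in their wild types, 28811482 to 46722325 in the Ezh2b mutant libraries and 29444354 to 54070380 in their wild types. In a principal component analysis the first component held 54.9% of the variance and the second 12.7%. The first component separated the Ezh2a set from the Ezh2b set. All Ezh2a libraries, mutant and wild type, had negative scores on it and all Ezh2b libraries positive ones. The Ezh2b mutant lay between its own wild type and the Ezh2a libraries. On the second component mutant and wild type had opposite signs within each set, with the mutant positive in Ezh2a and negative in Ezh2b. Sequencing depth of this size recovered 70% of simulated 1.25-fold changes and 100% of 2-fold changes in the Ezh2a comparison, for genes with an average log2 CPM of at least 1. All 12 libraries carried Y-linked counts (at least 6484 per library) and at most 10 counts of Xist, the transcript that silences an X chromosome in female cells.

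Ezh2 (GRCm38 chromosome 6, 47530139 to 47595341, minus strand) fell in the Ezh2a mutant and was level in the Ezh2b mutant. It stood at 30.3 ± 0.201 CPM (SD, n = 3) in the Ezh2a wild type and at 14.5 ± 0.554 in the Ezh2a mutant. This is a log2 fold change of -1.07 (SE 0.05, adjusted p = 3.4e-11), with all 3 mutant libraries below all 3 wild-type libraries. In the Ezh2b pair it stood at 35.0 ± 1.02 in the wild type and 35.1 ± 1.43 in the mutant, a log2 fold change of 0.00 (SE 0.05, adjusted p = 0.97). The difference between the Ezh2b and the Ezh2a effect was 1.07 (SE 0.07, adjusted p = 8.4e-10). Counts are summed over the gene, so these values do not say which isoform was present.

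**Figure D1:**
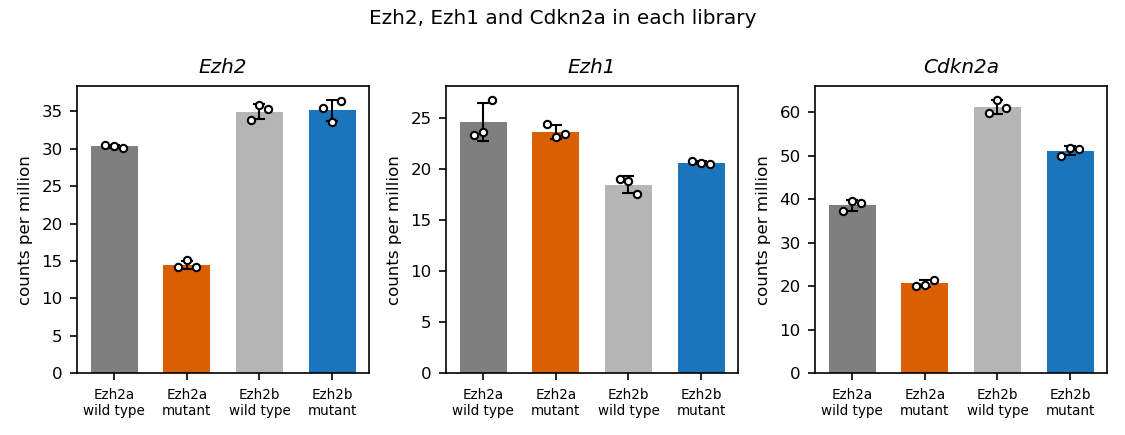
CPM of Ezh2, Ezh1 and Cdkn2a in the 4 groups, with 1 open point per library, bars at the mean of 3 libraries and error bars of 1 SD. Ezh2 averaged 14.5 in the Ezh2a mutant and 30.3 to 35.1 in the other groups.

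Ezh1 (chromosome 11, 101191115 to 101226463), which encodes the other methyltransferase of PRC2, did not pass the test in either mutant. Its log2 fold change was -0.06 (SE 0.06, adjusted p = 0.589) in Ezh2a and 0.16 (SE 0.06, adjusted p = 0.056) in Ezh2b. Cdkn2a (chromosome 4, 89274471 to 89294653), a cell-cycle inhibitor locus that PRC2 is known to silence, fell in both. In the Ezh2a pair it went from 38.7 ± 1.27 to 20.7 ± 0.775 CPM (log2 fold change -0.90, SE 0.05, adjusted p = 6.3e-11). In the Ezh2b pair it went from 61.2 ± 1.59 to 51.2 ± 1.00 CPM (log2 fold change -0.26, SE 0.04, adjusted p = 8.9e-05). Among 14 tested PRC2 subunits Ezh2 alone fell in the Ezh2a mutant and none rose, also when adjusted over the list alone. In the Ezh2b mutant 1 rose and 3 fell (2 and 4 adjusted over the list alone), among them Rbbp7 (-0.18, SE 0.03) and Aebp2 (-0.25, SE 0.05). The PRC2 list itself did not pass the test in either comparison (adjusted p = 0.0948 and 0.369).

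In the Ezh2a mutant the list of cartilage and bone genes rose and the inflammatory and epithelial lists fell, with either correlation in the camera test. Interferon-stimulated genes also fell, but their list passed only with the preset correlation (adjusted p = 0.236 with an estimated one). Col2a1, the type II collagen of cartilage (chromosome 15, 97975602 to 98004695), rose from 1.15 ± 0.0956 to 123 ± 6.36 CPM. Its log2 fold change of 6.75 (SE 0.12, adjusted p = 3.6e-18) was the largest of the genes named by the rule. Krt18, a keratin of simple epithelia (chromosome 15, 102028180 to 102032027), went from 9.91 ± 0.809 down to 1.04 ± 0.137 CPM, a log2 fold change of -3.25 (SE 0.16, adjusted p = 4.0e-11). The macrophage markers, by contrast, stayed at 0.182% ± 0.00287 of counts in the wild type and 0.176% ± 0.00613 in the mutant (SD, n = 3).

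Of 20 tested cartilage and bone genes, 13 rose and 1 fell in the Ezh2a mutant (14 and 1 adjusted over the list alone). Beside Col2a1 these included Acan (aggrecan, 3.22, SE 0.13), Col9a1 (a type IX collagen chain, 3.63, SE 0.24) and Matn4 (a matrilin, 2.34, SE 0.16). The list passed the camera test with an adjusted p of 1.3e-26, and adjusted p = 6.8e-05 with an estimated correlation. Col2a1 was also higher in the Ezh2b wild type than in the Ezh2a wild type (log2 difference 2.48), so its level varies without a mutation. Whether the cartilage rises reflect the cells present was not tested. Of 3 transcription factors among the other large rises, Pou3f4 rose from 0.415 ± 0.0549 to 23.1 ± 1.67 CPM (5.80, SE 0.14), Six2 from 0.884 ± 0.124 to 6.03 ± 0.221 CPM (2.77, SE 0.18) and Pou3f3 from 3.60 ± 0.147 to 17.0 ± 1.64 CPM (2.23, SE 0.12). Ntrk2, the receptor for brain-derived neurotrophic factor, rose by 3.70 (SE 0.15), Gfra2, a co-receptor for neurturin, by 2.60 (SE 0.13), and Clstn2, a calsyntenin, by 2.40 (SE 0.11). Igfbp2, which binds insulin-like growth factors, was the most abundant of these, at 36.8 ± 1.95 and 198 ± 10.3 CPM (2.43, SE 0.06). The adjusted p of the 10 largest rises ran from 3.6e-18 to 2.8e-09.

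Over the whole list of developmental transcription factors under Polycomb, 23 of 63 tested genes rose and 14 fell (25 and 14 adjusted over the list alone). The list moved up with a median log2 fold change of 0.14, but adjusted p = 0.291 with an estimated correlation. Members that fell were Gata2 (-1.82, SE 0.15), Tbx3 (-0.96, SE 0.08) and Pitx1 (-0.69, SE 0.06), the last a regulator of hindlimb identity. Of 34 tested Hox genes, which encode position along the body and limb axes, 4 rose and 14 fell, with the same counts adjusted over the list alone. The Hox list did not pass the test (adjusted p = 0.0858). Hoxa11 (-0.79, SE 0.08) and Hoxc10 (-0.78, SE 0.10) fell and Hoxa2 rose (1.48, SE 0.19). Among Hox genes of groups 10 to 13, 8 of 9 fell and none rose, and among groups 1 to 9, 4 of 25 rose and 6 fell.

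All 33 tested interferon-stimulated genes fell in the Ezh2a mutant, also when adjusted over the list alone, with a median of -0.79. Irf7 fell by 1.38 (SE 0.23), Cxcl10 by 1.18 (SE 0.20) and Ifit3b by 1.39 (SE 0.25), the last of which may share reads with its close paralog Ifit3. Their levels also varied within groups. The mean log2 CPM of the list was 4.18, 4.58 and 4.82 in the wild-type libraries and 3.81, 3.35 and 3.73 in the mutant libraries, and the list had adjusted p = 0.236 with an estimated correlation. Among 24 tested inflammatory cytokines and chemokines 12 fell and 2 rose, with the same counts adjusted over the list alone. The monocyte attractants Ccl7 (-0.96, SE 0.07) and Ccl2 (-0.75, SE 0.07) fell, and the list had adjusted p = 0.00573 with an estimated correlation. Of 20 macrophage markers 2 rose and 4 fell, with the same counts adjusted over the list alone. Lyz2 fell (-0.33, SE 0.04) while Mrc1 rose (0.41, SE 0.06), and the list did not pass the test (adjusted p = 0.464).

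Further genes with large falls were the steroid receptors Pgr (4.01-fold lower, SE of its log2 value 0.13) and Esr1 (-1.60, SE 0.12), Zbtb8b (-2.29, SE 0.24), the orphan receptor Gpr149 (-2.28, SE 0.15), the transporter gene Slco5a1 (-1.63, SE 0.16), the Wnt antagonist Frzb (-1.61, SE 0.14) and the glutamate receptor subunit Grin3a (-1.50, SE 0.14). Des, which encodes the intermediate filament of muscle, fell from 109 ± 3.75 to 34.2 ± 1.19 CPM (-1.67, SE 0.05). The adjusted p of the 10 largest falls ran from 3.9e-15 to 1.1e-06. Of 12 tested skeletal muscle genes 3 fell and none rose, with the same counts adjusted over the list alone: Des, Myh1 (-1.38, SE 0.15) and Acta1 (-0.86, SE 0.14). That list had adjusted p = 0.0147 with an estimated correlation. Of 12 epithelial genes 4 fell and 1 rose (5 and 1 adjusted over the list alone), among them Krt18 and its partner keratin Krt8 (-2.88, SE 0.28), with adjusted p = 0.0451 with an estimated correlation. Some genes of the mesothelium, picked after their values were seen, were lower in the same mutant libraries. Msln went from 41.3 ± 1.06 to 21.8 ± 0.324 CPM of total counts, Upk3b from 14.3 ± 1.12 to 10.4 ± 0.759, Wt1 from 3.76 ± 0.211 to 2.27 ± 0.503 and Muc16 from 3.93 ± 0.691 to 2.04 ± 0.361. On that scale Krt18 went from 9.88 to 1.07 and Krt8 from 3.04 to 0.417, larger falls that those genes do not account for. A mesothelial list chosen without looking at its values did not fall as a set, with 2 of 8 tested genes higher, 1 lower and a median of -0.12. Whether the keratin falls reflect the cells present was not tested further. Contractile genes fell in 10 of 22 cases and rose in 2 (11 and 2 adjusted over the list alone), and their list had adjusted p = 0.174 with an estimated correlation.

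Genes of G2 and mitosis rose in the Ezh2a mutant. Of 36 tested, 32 rose and none fell (33 and none adjusted over the list alone), with a median of 0.26 and adjusted p = 0.0348 with an estimated correlation. Examples are Cenpf (0.39, SE 0.04), Ccna2 (0.41, SE 0.05) and Mki67 (0.29, SE 0.04). Of 42 DNA replication genes 10 rose and none fell, with the same counts adjusted over the list alone (adjusted p = 0.215 with an estimated correlation). Of 19 cell-cycle inhibitor and senescence genes 10 fell and 5 rose (10 and 6 adjusted over the list alone), with adjusted p = 0.0364 with an estimated correlation. They include Cdkn2a, Ccl2 and Igfbp7 (-0.45, SE 0.04). Imprinted genes, expressed from 1 parental allele, rose in 9 of 40 cases and fell in 6 (16 and 6 adjusted over the list alone), and their list had adjusted p = 0.0935 with an estimated correlation. Dlk1 (1.64, SE 0.06), Zdbf2 (1.51, SE 0.07) and Plagl1 (1.05, SE 0.06) rose and Peg3 fell (-0.48, SE 0.04). Among 22 subunits of PRC1, the other Polycomb complex, 7 rose and none fell, also when adjusted over the list alone. Bmi1 (0.68, SE 0.04) and Rnf2 (0.22, SE 0.04) led them, and the list had adjusted p = 0.212 with an estimated correlation.

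In all, 3118 of 15708 genes (19.8%) changed in the Ezh2a mutant, 1509 upward and 1609 downward, and 391 by at least 2-fold (253 up, 138 down). With library totals in place of TMM factors the split became 2061 up and 1117 down. Of 32 lists, 19 passed the camera test with the preset correlation and 6 with an estimated correlation. The other lists that passed only with the preset one were glycolysis and hypoxia (1 up, 17 down of 26, adjusted p = 0.174 with an estimated correlation), cholesterol synthesis (none up, 5 down of 24, 0.198), p53 targets (4 up, 13 down of 24, 0.0935), Hedgehog targets (4 up, none down of 10, 0.259), Y-linked genes (none up, 3 down of 4, 0.215), immediate early genes (2 up, 7 down of 23, 0.256) and Wnt targets (10 up, 3 down of 18, 0.146). Adjusted over the list alone these counts were 2 and 18, none and 8, 4 and 14, 4 and none, none and 3, 2 and 8, and 12 and 4. The lists of extracellular matrix, BMP and TGF-beta, unfolded protein response, germline, neural, histone and DNA methylation enzyme, mitochondrial, adipocyte, fibroblast and endothelial genes did not pass.

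In the Ezh2b mutant the macrophage list rose and the list of G2 and mitosis fell, with either correlation in the camera test. Contractile, matrix, DNA replication and Hox lists passed only with the preset correlation (adjusted p = 0.0601, 0.277, 0.0991 and 0.472 with an estimated one). All 20 macrophage and leukocyte markers rose (20 adjusted over the list alone), with a median log2 fold change of 2.06. Lyz2, the lysozyme of macrophages (chromosome 10, 117277331 to 117282321), rose from 36.1 ± 3.14 to 203 ± 2.52 CPM (2.50, SE 0.05, adjusted p = 1.5e-17). Penk, which encodes the precursor of enkephalins (chromosome 4, 4133531 to 4138819), fell from 399 ± 46.6 to 54.5 ± 1.78 CPM (-2.87, SE 0.07, adjusted p = 5.1e-16). All 3 mutant libraries lay beyond all 3 wild-type libraries for each gene named by size of change.

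Other macrophage markers moved by similar amounts. C1qc, a chain of complement C1q, rose by 2.18 (SE 0.06), Csf1r, the receptor for macrophage colony-stimulating factor, by 1.95 (SE 0.05), and Laptm5 by 2.19 (SE 0.07). The list had adjusted p = 5.3e-04 with an estimated correlation. The 20 genes together held 0.0118% ± 0.000537 of counts in the wild type and 0.0525% ± 0.00197 in the mutant. Several of the 10 largest rises are genes known from immune cells: Il21r (3.54, SE 0.27, and 4.42 without Ezh2b wild-type replicate 3), P2ry12 (2.77, SE 0.27), Fcgr2b (2.75, SE 0.18), Gpr65 (2.64, SE 0.29), Rac2 (2.62, SE 0.19) and Ccr1 (2.62, SE 0.24). AI662270, a gene known by its clone name, rose by 3.05 (SE 0.30). Mmp13, a collagenase, rose from 0.636 ± 0.173 to 9.29 ± 1.06 CPM (3.80, SE 0.15), and Muc16, a mucin of mesothelial surfaces, from 0.345 ± 0.0567 to 2.29 ± 0.299 CPM (2.66, SE 0.24). Acan rose as in the Ezh2a mutant (2.64, SE 0.18), though to a lower level, 2.97 ± 0.482 CPM. The adjusted p of these 10 rises ran from 5.6e-13 to 6.5e-07.

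**Figure D2:**
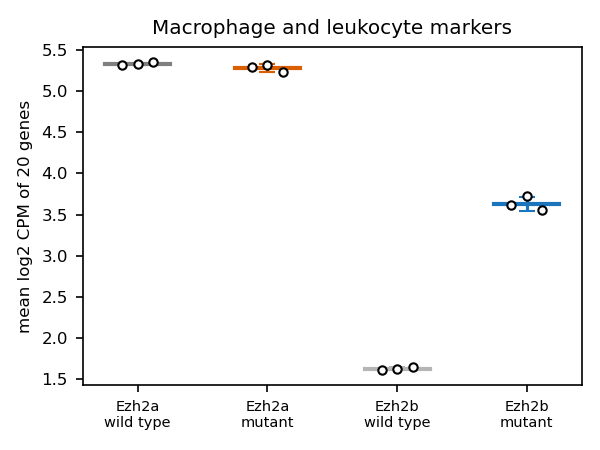
Mean log2 CPM of the 20 macrophage and leukocyte markers in each library (open points), with the mean of the group (horizontal line) and 1 SD (error bar). The Ezh2b groups lie below both Ezh2a groups, with the Ezh2b wild type lowest.

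The largest falls in the Ezh2b mutant included, after Penk, Sema3d, a secreted guidance cue, from 97.5 ± 5.31 to 18.6 ± 2.1 CPM (-2.40, SE 0.06). Thbs4 (-2.23, SE 0.16) and Comp (-1.90, SE 0.10) encode related matrix proteins of tendon and cartilage. Fgf5 (-2.14, SE 0.14), Lrrtm3 (-2.08, SE 0.09), Cacna2d3 (-1.95, SE 0.17), the nuclear receptor Esrrg (-1.91, SE 0.11), the urea transporter Slc14a1 (-1.80, SE 0.14) and Kirrel3 (-1.74, SE 0.16) complete the 10 named falls, whose adjusted p ran from 5.1e-16 to 5.1e-08. Of the 20 cartilage and bone genes 3 rose and 4 fell (4 and 6 adjusted over the list alone), Acan among the first and Comp among the second, and the list did not pass the test (adjusted p = 0.314).

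Hox genes of the Ezh2b mutant changed in opposite directions along the HoxA and HoxD clusters, while the HoxB and HoxC clusters had no falls. Of 34 tested, 21 rose and 7 fell (23 and 8 adjusted over the list alone), and the list had adjusted p = 0.472 with an estimated correlation. In groups 1 to 9, 20 of 25 rose and none fell, with a median of 0.84. In groups 10 to 13, 1 of 9 rose (Hoxc10) and 7 fell, all of HoxA or HoxD, with a median of -0.64. No tested HoxB gene belonged to groups 10 to 13. From Hoxc5 on, the HoxC rises shrank along the cluster, from 1.22 for Hoxc5 to 0.36 for Hoxc10, but Hoxc4 rose by only 0.875. Hoxd13 went from 123 ± 10.6 to 54.2 ± 2.55 CPM (-1.18, SE 0.05), Hoxd12 (-1.05, SE 0.08) and Hoxd11 (-1.02, SE 0.08) fell beside it, and Hoxc6 rose (0.91, SE 0.07). The macrophage share of counts differed between these same libraries. Among 63 other developmental transcription factors 22 rose and 17 fell, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.803). The limb factors Lhx9 (-0.87, SE 0.04) and Tbx4 (-0.87, SE 0.06) fell, and Meis1, which marks the proximal limb, rose (0.91, SE 0.06).

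**Figure D3:**
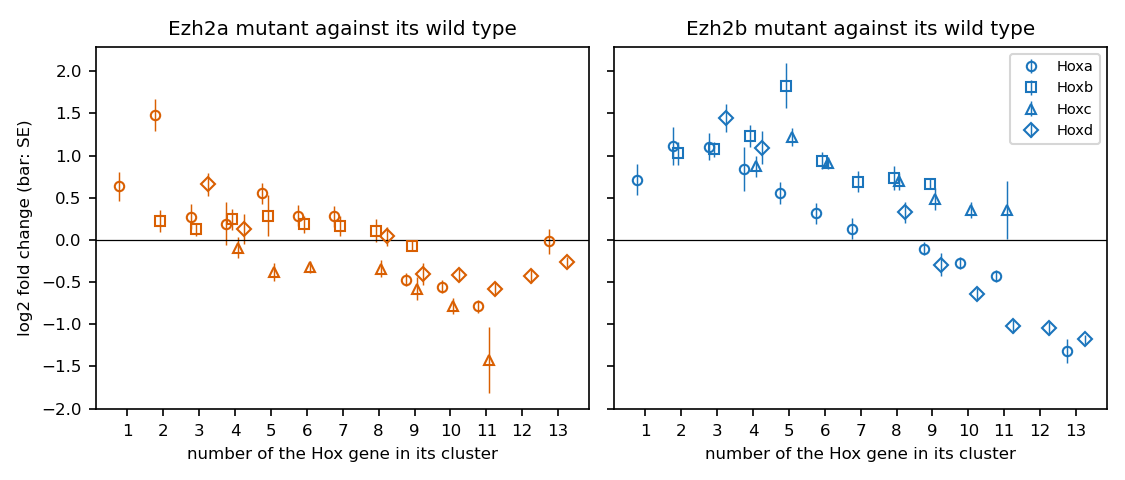
Log2 fold change of each tested Hox gene (vertical axis, error bar of 1 SE) against its number within the cluster (horizontal axis), for the Ezh2a mutant on the left and the Ezh2b mutant on the right, with a marker shape per cluster. In groups 10 to 13 the medians are -0.56 and -0.64, and in groups 1 to 9 they are 0.16 and 0.84.

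Cell-division genes fell in the Ezh2b mutant, from a wild-type level above that of the Ezh2a wild type. Of 36 genes of G2 and mitosis 35 fell and none rose (36 and none adjusted over the list alone), with a median of -0.36 and adjusted p = 0.0357 with an estimated correlation. Cdc20 (-0.45, SE 0.04) and Anln (-0.48, SE 0.04) had the smallest p. Of 42 DNA replication genes 28 fell and none rose (33 and none adjusted over the list alone), with adjusted p = 0.0991 with an estimated correlation. Mcm5 (-0.40, SE 0.05) and Lig1 (-0.29, SE 0.04) were among them. Cell-cycle inhibitor and senescence genes rose in 9 of 19 cases and fell in 4, with the same counts adjusted over the list alone and adjusted p = 0.0601 with an estimated correlation. Members with the smallest p were Mmp13 and Igfbp5 (1.05, SE 0.06), both secreted proteins, while Cdkn2a fell. The rise in the macrophage share, 0.0118% to 0.0525% of counts, was in the same libraries.

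Contractile genes rose in 14 of 22 cases and fell in 2 (15 and 2 adjusted over the list alone), with adjusted p = 0.0601 with an estimated correlation. Des (1.38, SE 0.05), Actg2 (1.21, SE 0.06) and Myh11 (1.10, SE 0.06) led them. Of 46 collagen and matrix genes 25 rose and 6 fell (26 and 7 adjusted over the list alone; adjusted p = 0.277 with an estimated correlation), among them the collagen crosslinking enzyme Loxl2 (1.00, SE 0.03), Thbs2 (0.94, SE 0.04) and Vcan (0.54, SE 0.03). Fibroblast markers rose in 11 of 18 cases and fell in 5 (11 and 6 adjusted over the list alone; adjusted p = 0.261 with an estimated correlation), with Fap (1.17, SE 0.08) and Dpt (0.99, SE 0.07) rising. Imprinted genes rose in 17 of 40 cases and fell in 4 (18 and 4 adjusted over the list alone; adjusted p = 0.111 with an estimated correlation). Peg3 (0.87, SE 0.04), Smoc1 (1.15, SE 0.08) and Zdbf2 (1.18, SE 0.08) rose. Cholesterol synthesis genes fell in 16 of 24 cases and rose in 1 (17 and 1 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation). Insig1, a brake on sterol synthesis, was among those that fell (-0.29, SE 0.03). The macrophage share was higher in the same mutant libraries in which these groups moved, and so were 5 of 8 tested genes of the mesothelial list, with none lower.

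In all, 4105 genes (26.1%) changed in the Ezh2b mutant, 2200 upward and 1905 downward, and 783 by at least 2-fold (623 up, 160 down). With library totals in place of TMM factors the split became 1910 up and 2525 down. Of 32 lists 11 passed the camera test with the preset correlation, and 2 with an estimated correlation: macrophage markers, and G2 and mitosis. The remaining list that passed with the preset correlation was p53 targets (10 up, 1 down of 24, and 10 and 2 adjusted over the list alone), with adjusted p = 0.232 with an estimated correlation. Interferon-stimulated genes did not pass (1 up, 2 down of 33, and none and 1 adjusted over the list alone; adjusted p = 0.234), and Ifit2 fell (-0.43, SE 0.09). The lists of immediate early, BMP and TGF-beta, Wnt, skeletal muscle, Hedgehog, neural, unfolded protein response, inflammatory, histone and DNA methylation enzyme, epithelial, Y-linked, mitochondrial, PRC1, endothelial, germline, glycolysis and adipocyte genes did not pass either.

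Most of the genes named so far differed between the Ezh2b and the Ezh2a effect. A high share was to be expected, since many were picked for a large change in either mutant. Over all tested genes the share was 26.5%. Both wild types enter this difference, so it cannot be credited to the mutations alone. The difference between the Ezh2b and the Ezh2a effect was positive for Mmp13 (4.61, SE 0.19), Krt18 (4.12, SE 0.25), Muc16 (3.66, SE 0.29), Serpinb6b (3.46, SE 0.19) and Il21r (3.27, SE 0.32, and 4.14 without Ezh2b wild-type replicate 3). Serpinb6b belongs to a family of close paralogs, so its counts are less certain. The difference was negative for Col2a1 (-7.84, SE 0.19), Pou3f4 (-5.15, SE 0.30), Ntrk2 (-4.87, SE 0.32), Sema3d (-3.26, SE 0.09) and Igfbp2 (-3.17, SE 0.08). Adjusted p of these 10 genes ran from 3.8e-16 to 2.2e-07, and Cdkn2a fell less in Ezh2b (0.65, SE 0.06, adjusted p = 1.8e-07). The test of the difference passed for 4168 genes, 2305 positive and 1863 negative, of which 361 had passed in neither mutant alone. With library totals in place of TMM factors there were 1723 positive and 2787 negative.

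Cell-division genes differed between the effects: the difference was negative for 35 of 36 genes of G2 and mitosis and positive for none, with a median of -0.61. Macrophage markers were positive in 20 of 20, contractile genes in 15 of 22 with 1 negative, and inflammatory genes in 13 of 24 with 3 negative. Cartilage and bone genes were negative in 11 of 20 with 1 positive. Adjusted over the list alone these counts were 35 negative, 20 positive, 17 positive with 1 negative, 15 positive with 4 negative, and 14 negative with 1 positive. Of 32 lists 14 differed by the camera test and 9 with an estimated correlation, these 5 among them. Both wild types enter these differences. The mean log2 CPM of the G2 and mitosis list was 5.66 to 5.69 in the Ezh2b wild type and 5.29 to 5.34 in its mutant. It was 5.23 to 5.29 in the Ezh2a wild type and 5.49 to 5.53 in its mutant. The Ezh2b wild type stood highest, so the negative difference cannot be credited to the mutations alone.

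Across the 15708 genes the log2 fold changes of the mutants had a Pearson r of -0.02 and a Spearman rho of -0.08. Genes are not independent replicates, so no p is attached. Among 1506 genes that changed in both, 570 (37.8%) moved the same way. Genes up in Ezh2a and down in Ezh2b numbered 437, against 183 for independent lists, and genes down in Ezh2a and up in Ezh2b numbered 499, against 225. Genes up in both numbered 340, against 211, and genes down in both 230, against 195. Every combination of directions exceeded this baseline, which takes each gene as equally easy to call. Genes that are easier to call pass in both tests more often, so the excess is not in itself a sign of linked effects. Acan, Zdbf2 and Meis1 illustrate shared rises and Hoxa11 and Cdkn2a shared falls, while Des, Peg3 and Sema3d moved in opposite directions.

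**Figure D4:**
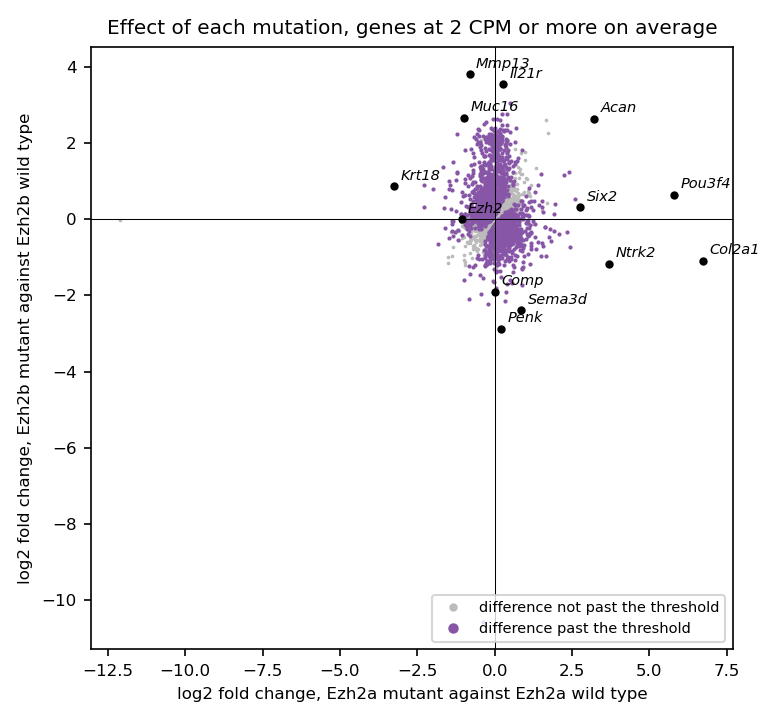
Log2 fold change of the Ezh2a mutant (horizontal) and of the Ezh2b mutant (vertical), each against its own wild type, for tested genes at 2 CPM or more on average. Purple points passed the test of the difference, grey points did not, and black points are named genes such as Col2a1 (6.75 in Ezh2a) and Penk (-2.87 in Ezh2b).

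**Figure D5:**
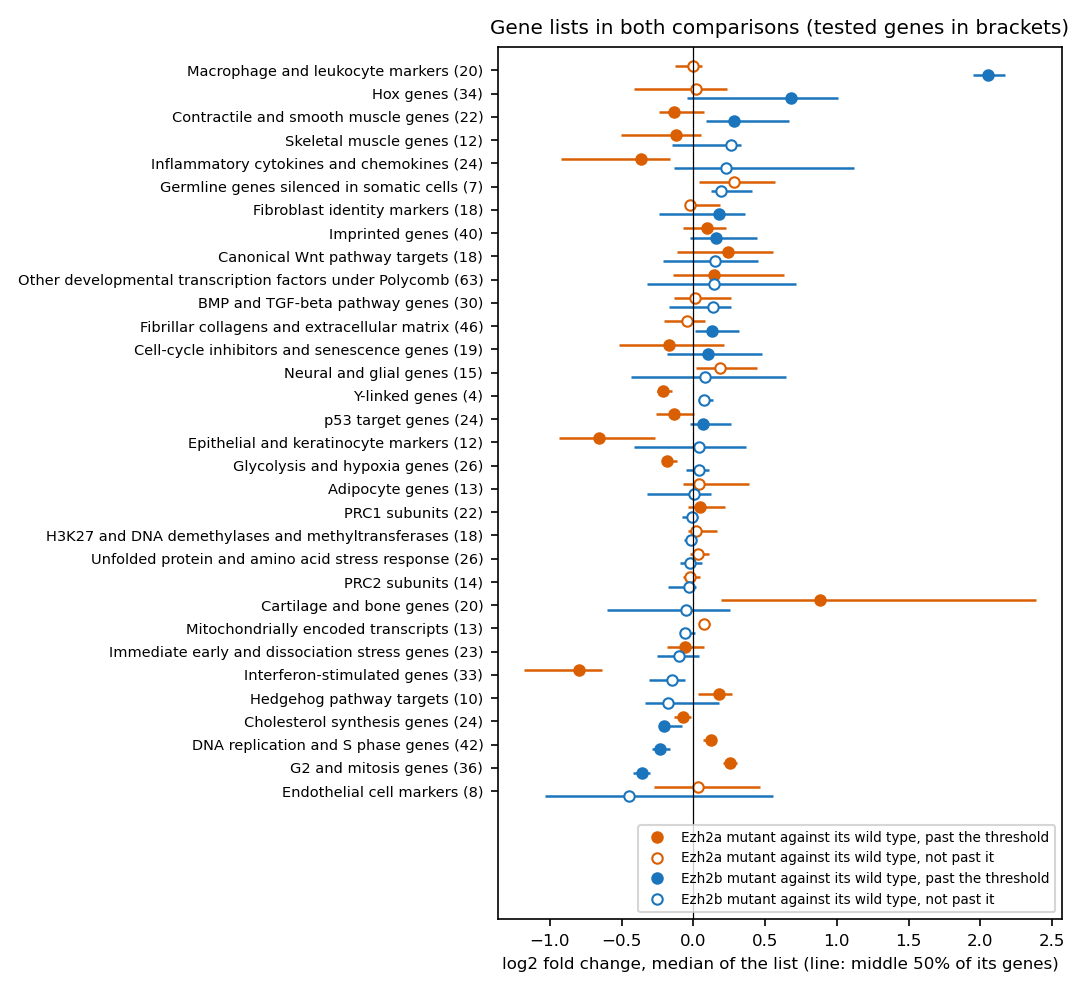
Median log2 fold change of each of 32 gene lists in the Ezh2a mutant (orange) and the Ezh2b mutant (blue), with lines over the middle 50% of its genes and filled points for lists that passed the camera test with the preset correlation. Macrophage markers stand at 2.06 in Ezh2b, and cartilage and bone genes at 0.88 in Ezh2a.

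The wild types of the 2 sets, which carry no mutation, also differed. In the Ezh2b wild type the myosins Myh2 (3.78, SE 0.20) and Myh1 (2.61, SE 0.11), Esrrg (2.77, SE 0.12) and Col2a1 (2.48, SE 0.16) were higher than in the Ezh2a wild type. Lower were Brinp3 (-5.35, SE 0.22), Zbtb8b (-5.34, SE 0.33), the oestrogen-response gene Greb1 (-4.96, SE 0.15) and Fcgr2b (-4.80, SE 0.15). The adjusted p of these 8 genes ran from 1.1e-15 to 2.2e-10. Evi2 stood at 7.01 ± 1.57 CPM in the Ezh2a wild type, against 4 counts in 1 Ezh2b wild-type library and 0 in the others (adjusted p = 6.2e-05). All 20 macrophage markers were lower (20 adjusted over the list alone), with a median of -3.72 and adjusted p = 1.7e-04 with an estimated correlation. All 36 genes of G2 and mitosis were higher (36 adjusted over the list alone), with a median of 0.44 but adjusted p = 0.132 with an estimated correlation. Ezh2 was higher (0.21, SE 0.05, adjusted p = 0.0017), Ezh1 lower (-0.42, SE 0.06) and Cdkn2a higher (0.66, SE 0.04). In all 6642 genes (42.3%) differed, 3212 higher and 3430 lower in the Ezh2b wild type, and 1320 by at least 2-fold. Of 32 lists 9 passed and 1 with an estimated correlation. Litter, line, culture and processing day are not separated in this comparison, and each mutant set shares them with its own wild type only as far as the labels say.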

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

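The effects of the Ezh2a and Ezh2b mutations were compared gene by gene by the interaction contrast, and 89 of the 96 genes named for the mutants or for their difference passed it. A high share was to be expected, since these genes were picked for large changes or for the difference itself, and over all tested genes the share was 26.5%. Of the 32 gene lists 14 passed, and 9 with an estimated correlation. All values in the next paragraphs are the Ezh2b effect minus the Ezh2a effect on the log2 scale.

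Among the genes named for Ezh2a, by size of change or as list members (Col9a1, Krt8), the difference was -7.84 for Col2a1, -5.15 for Pou3f4, -4.87 for Ntrk2, -4.15 for Col9a1, -3.17 for Igfbp2, -2.68 for Matn4, -2.46 for Six2, -2.08 for Gfra2, -1.16 for Clstn2 and -1.07 for Pou3f3. It was 4.70 for Krt8, 4.12 for Krt18, 3.18 for Gpr149, 3.05 for Des, 2.79 for Pgr, 2.61 for Zbtb8b, 2.19 for Frzb, 1.93 for Slco5a1, 1.36 for Esr1 and 1.17 for Gata2. Acan (-0.58, adjusted p = 0.106) and Grin3a (0.36, adjusted p = 0.178), picked for size as well, did not pass. Ezh2 differed by 1.07 and Cdkn2a by 0.65.

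Among the genes picked for a large change in Ezh2b, or for the difference itself (Serpinb6b), the difference was 4.61 for Mmp13, 3.66 for Muc16, 3.46 for Serpinb6b, 3.27 for Il21r, 2.69 for Gpr65, 2.56 for AI662270, 2.55 for Rac2, 2.52 for Fcgr2b, 2.46 for Ccr1 and 2.37 for P2ry12. It was -3.26 for Sema3d, -3.08 for Penk, -2.63 for Kirrel3, -2.47 for Fgf5, -2.27 for Esrrg, -2.02 for Thbs4, -1.91 for Comp, -1.86 for Slc14a1, -1.51 for Cacna2d3 and -1.24 for Lrrtm3.

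Macrophage markers differed by a median of 2.04, with 2.83 for Lyz2, 2.12 for C1qc, 1.96 for Csf1r, 1.95 for Laptm5 and 1.64 for Mrc1. Genes of G2 and mitosis differed by a median of -0.61, with -0.86 for Ccna2, -0.74 for Cenpf, -0.62 for Mki67, -0.60 for Cdc20 and -0.58 for Anln. DNA replication genes differed by -0.36, with -0.61 for Mcm5 and -0.46 for Lig1. Contractile genes differed by 0.40, with 1.21 for Actg2 and 0.67 for Myh11, and skeletal muscle genes by 0.39, with 1.19 for Acta1. Cartilage and bone genes differed by -0.93, collagen and matrix genes by 0.15 (1.40 for Loxl2, 1.10 for Thbs2, 1.03 for Vcan; adjusted p of the list 0.369 with an estimated correlation), and the fibroblast markers Fap and Dpt by 1.21 and 1.00.

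Inflammatory genes differed by a median of 0.73, with 1.00 for Ccl2 and 0.91 for Ccl7. Interferon-stimulated genes differed by 0.65, with 1.35 for Irf7, 1.08 for Ifit3b and 0.91 for Cxcl10, but 13 of 33 genes passed and the list had adjusted p = 0.778 with an estimated correlation. Senescence genes differed by 0.34 (1.08 for Igfbp7, 0.76 for Igfbp5), p53 targets by 0.26, glycolysis genes by 0.20 and Hedgehog targets by -0.30. Hox genes differed by a median of 0.64, with 1.23 for Hoxc6, 1.14 for Hoxc10, 0.36 for Hoxa11, -0.45 for Hoxd11, -0.62 for Hoxd12 and -0.92 for Hoxd13. With an estimated correlation the glycolysis, Hedgehog and Hox lists did not pass (adjusted p = 0.396 each). The other developmental factors were at 1.08 for Tbx3, 0.77 for Pitx1, 0.33 for Meis1, -0.60 for Lhx9 and -0.74 for Tbx4. Imprinted genes were at 1.61 for Smoc1, 1.36 for Peg3, -0.33 for Zdbf2, -1.14 for Plagl1 and -1.84 for Dlk1. Polycomb genes were at -0.83 for Bmi1, -0.20 for Rnf2 and -0.16 for Rbbp7, and the sterol gene Insig1 was at -0.34.

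3 patterns were weighed, and 4 of the tests used for them were chosen after the result was seen: the macrophage difference between the wild types, Hox groups 10 to 13, the mitosis genes for Ezh2, and the summed Ezh2 counts. The first pattern is the rise of macrophage markers in the Ezh2b mutant. Unequal depth argues poorly for it, since after thinning every library to the smallest total the median log2 change was still 2.06. A higher share of macrophages in the mutant cultures is a candidate explanation: of a second macrophage list of 20 genes, none in the fixed lists, 84.2% of the 19 tested genes rose, with a median of 1.84. Whether the mutation set that share cannot be told, because the wild types of the 2 sets, which carry no mutation, differed by a median of -3.72, so the share also varies without it.

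The second pattern is the opposite movement along the HoxA and HoxD clusters in the Ezh2b mutant. HoxB and HoxC had no falls, but no tested HoxB gene was numbered above 9. From Hoxc5 on, the HoxC rises shrank along the cluster, from 1.22 for Hoxc5 to 0.36 for Hoxc10, but Hoxc4 rose by only 0.875. A rise of all Hox genes was not seen, because 7 of the 9 genes of groups 10 to 13 fell, with a median of -0.64. In the Ezh2b wild type 6 of these genes also stood higher than in the Ezh2a wild type. Loss of Polycomb repression at all Hox genes is not decided by this, because a change in the cells present could lower these genes as well. Cells from other body regions, with less distal limb, may be present: a list of 9 distal limb genes chosen without looking at their values had a median of -0.34, with 4 of 8 tested genes lower and 1 higher. The Ezh2a mutant gave a similar median of -0.32 for that list. In the Ezh2b wild type against the Ezh2a wild type its median was 0.36, with 4 genes higher and 2 lower. The list thus varies between cultures without a mutation, and the Ezh2b wild type also enters the Ezh2b effect. A biological effect of either mutation on positional genes stays open and untested.

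The third pattern is the lower Ezh2 level in the Ezh2a mutant. Ezh2 is known to be higher in dividing cells, but fewer dividing cells are argued against, since the genes of G2 and mitosis rose, with a median of 0.26. A loss of reads from the edited transcript in alignment or counting cannot be told apart from a lower level, because the log2 change of -1.07 is a sum over the gene with no exon values. A direct effect of the mutation on the transcript is the biological explanation, also untested.

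Other splits of the samples were counted in the fit over 12 libraries. Each pair allows 10 splits of 3 against 3, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each comparison. For Ezh2a it gave 3118 genes against 1 in the highest other split, for Ezh2b 4105 against 0, and for the wild types 6642 against 0. For gene lists, with too few splits as well, the real value was 19 lists in Ezh2a against 9 in the highest other split, and 11 in Ezh2b against 10. For the difference between the effects, 100 splits were drawn within the pairs, and only the real one, with 4168 genes, reached that number (highest other 3370). The split with 3370 had the real correlation of effects with its sign reversed (0.017), so it was the real grouping with names exchanged in 1 pair. Most splits mixed mutant and wild type, so they do not show what equal effects in the 2 pairs would give. Chance differences between cultures are therefore not excluded. The correlation of -0.02 between the effects was matched in size by 87 of 100 splits (highest other 0.23), so chance cannot be excluded for it.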

How the results depend on the processing

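All counts of genes stayed within 1.5 times the reported one under the alternatives run, apart from the 2-fold threshold. Thinning, counts divided by 2 and leaving out the 2 deepest Ezh2b libraries were chosen after seeing the data. At least 2-fold, the counts were 391 (Ezh2a), 783 (Ezh2b), 1013 (difference) and 1320 (wild types), fewer by construction. With an estimated correlation 6 lists passed in Ezh2a and 2 in Ezh2b. The Ezh2 change in the Ezh2b mutant is near 0 and turned sign with library totals (-0.027) and limma-voom (-0.0012), and ran from -0.018 to 0.044 over left-out libraries; the cause was not tested. The correlation of effects was 0.0041 with 1 CPM in 3 libraries, -0.054 without the 2 deepest libraries, and -0.063 to 0.0098 over left-out libraries; the cause was not tested. Ezh1 in Ezh2a ran from -0.094 (without Ezh2a wild-type replicate 1) to 0.0079 (without replicate 3), and in Ezh2b it passed the threshold under several alternatives (adjusted p 0.0393 to 0.0490 in those). Of 2207 recomputed values of named genes, 2199 kept their direction and side of the threshold, 6 became significant, 1 turned sign and 1, Evi2 between the wild types, lost significance with limma-voom (adjusted p = 0.0525). Evi2 there ran from -10.96 to -6.64 over left-out libraries.

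Leaving out 1 library at a time gave 2296 to 2556 genes in Ezh2a, 3405 to 3946 in Ezh2b, 3728 to 4321 for the difference and 5834 to 6474 for the wild types. Same-numbered libraries did not deviate together (correlations of -0.048 to 0.037), so the numbers gave no sign of paired samples. Where libraries differ by little more than sampling noise, a shared origin could go unseen. With the replicate block 3081, 4065, 4111 and 6615 genes passed and Ezh2 in Ezh2a was at -1.07. Fits to the 6 libraries of a pair gave 3805 genes in Ezh2a and 3380 in Ezh2b. At this depth 70% of 1.25-fold changes were recovered in simulation for genes with an average log2 CPM of at least 1. Smaller changes, and changes of genes at lower levels, can be missed.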

Other observations

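Genes of the mesothelium, the lining of body cavities, were looked at after their values were seen. In CPM of total counts (SD, n = 3), Msln stood at 41.3 ± 1.06 in the Ezh2a wild type, 21.8 ± 0.324 in the Ezh2a mutant, 6.83 ± 0.901 in the Ezh2b wild type and 12.95 ± 0.802 in the Ezh2b mutant. Upk3b ranked the groups alike, at 14.3 ± 1.12, 10.4 ± 0.759, 1.36 ± 0.0939 and 6.71 ± 0.431 CPM, as did Wt1, at 3.76 ± 0.211, 2.27 ± 0.503, 0.281 ± 0.0303 and 1.45 ± 0.302 CPM. Muc16 was also highest in the Ezh2a wild type (3.93) and lowest in the Ezh2b wild type (0.345). Its Ezh2b mutant level (2.23 ± 0.291) was not below that of the Ezh2a mutant (2.04 ± 0.361). A smaller share of mesothelial cells in the Ezh2b wild-type cultures is a candidate explanation. Of a list of 9 mesothelial genes chosen without looking at their values, 87.5% of the 8 tested were lower in the Ezh2b wild type than in the Ezh2a wild type, with a median of -2.30, and 5 of the 8 rose in the Ezh2b mutant. In the Ezh2a mutant 2 of the 8 rose and 1 fell, with a median of -0.12, so the list did not follow the fall of Msln, Upk3b and Wt1 there.

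The Ezh2b mutant had 623 genes at least 2-fold higher and 160 at least 2-fold lower. Genes that follow the macrophage share are a candidate for part of this. Of the 623 genes, 315 (50.6%) were at least 2-fold higher again in the Ezh2a wild type, where the macrophage share was larger, against 34 (21.2%) of the 160 lower genes and 4.59% of all tested genes. Msln, Upk3b and Wt1 have the same order of these 3 groups, so this count does not separate the 2 cell types. On the first principal component the Ezh2b mutant also lay between its wild type and the Ezh2a libraries. Any gene that follows that difference between the sets would be counted, so the 50.6% does not single out macrophages.

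DNA linked to the edited gene could carry effects of its own. Of 122 tested genes within 10 Mb of Ezh2, leaving out Ezh2 itself, 29 (23.8%) changed in the Ezh2a comparison, against 20.9% elsewhere (one-sided Fisher's exact test, p = 0.250, Benjamini-Hochberg 0.50 over 2 tests). In the Ezh2b comparison 34 (27.9%) changed, against 27.6% elsewhere (the same Fisher's exact test, p = 0.505, adjusted 0.505). These tests neither show nor exclude such an effect.

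Across 34 Hox genes the number of the gene in its cluster ran against the log2 fold change in both mutants, with a Spearman rho of -0.77 in Ezh2a and -0.85 in Ezh2b (Pearson r of -0.72 and -0.84). This relation was tested after it was seen, and genes are not independent replicates. A permutation test gave p = 1.0e-05 for both, the smallest it can give. The wild types differed the other way: 18 of 25 genes of groups 1 to 9 were lower and 6 of 9 genes of groups 10 to 13 higher in the Ezh2b wild type. That group enters this comparison and the Ezh2b effect with opposite signs, so the 2 are not separate observations. Hox levels particular to the Ezh2b wild type could give both. The mean log2 CPM of the Hox list was 2.25 to 2.54 in its libraries and 2.72 to 2.85 in those of the other groups.

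Gm33272, a long noncoding RNA gene on chromosome Y (90793687 to 90806846 in RefSeq GRCm38.p6), was chosen after its values were seen. It had 0 counts in all 3 Ezh2b mutant libraries, 5.39 ± 0.554 CPM in the Ezh2b wild type, 12.0 ± 0.382 in the Ezh2a wild type and 9.60 ± 1.04 in the Ezh2a mutant (SD, n = 3). Set against a floor of 3 counts per library, it was at least 61.9-fold lower in the Ezh2b mutant than in its wild type, for counting error alone. Evi2 was at 0 counts in Ezh2a mutant replicate 1 but at 303 and 243 counts in the other two.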
